A study of Mus musculus with 24 samples.

How the data were processed

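DNA methylation was measured in desheathed mouse sciatic nerve by reduced-representation bisulfite sequencing, in which MspI fragments are treated with bisulfite so that unmethylated cytosines read as thymine. Per the labels' protocols, nerves of mice of either sex were pooled before DNA extraction. The 24 samples reached the analysis as 16 call tables. The 8 tables of the developmental series (3 newborn, 3 at P10 and 2 at P60) hold 1 sample each. The 8 tables of the GNMT and db mice each join 2 samples of 1 group, per the labels, and each table was counted as 1 replicate. Replicates are separate pools as far as the labels say, so p-values measure the spread between tables, which may be partly technical.

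Per the submitters' processing notes, the tools named were CASAVA 1.8.2, Trim Galore, BSMAP and methylKit, and the genome build was mm9. Versions of the last 3 tools were not given in the sources used here. The deposited tables list, for each cytosine and strand, an estimated count of reads (the depth, with a fractional value at 22 to 362 cytosines per table) and the percent of reads methylated. Depths were rounded to whole reads, and methylated reads were taken as depth times percent divided by 100, also rounded. The highest depth listed was 65535, and the lowest was above 5 reads in every table. A level of 0% was listed at 3 to 177 cytosines per table, each with at least 2002 reads, where 1 methylated read rounds to 0 at the 1 decimal given. No listed cytosine was therefore shown to lack methylated reads. A cytosine without methylated reads was therefore not told apart from one without coverage, so a gain from 0 or a loss to 0 was not measured. Listed cytosines that lie next to each other on a strand, which cannot both be CpGs, numbered 881 to 19172 per table, so the tables also hold cytosines outside CpGs. Among the cytosines shared by all developmental tables there were only 16 such pairs.

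Cytosines on chromosomes 1 to 19 were kept when they had at least 10 reads in every table of a series and no more than the 99.9th percentile of depth in any. The series were development, GNMT and db, with 60516, 82360 and 70151 cytosines kept. Reads were summed over fixed tiles of 1000 bp with at least 3 such cytosines, which gave 8651, 11784 and 10396 tiles. Each tile was tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test on methylated and unmethylated reads with an intercept per table. The developmental fit held all 8 tables, and the GNMT and db fits held 4 each. P-values were adjusted by the Benjamini-Hochberg method over the tiles of a comparison. A tile was called at an adjusted p under 0.05 and a difference of at least 10 percentage points between group means. The tiles named are, per comparison, the 5 largest gains and the 5 largest losses among called tiles whose tables did not overlap between the groups. Where none was called, the tile of lowest p is named as chosen after its values were seen.

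The mean level of a table was the unweighted mean over the shared cytosines. Group means were compared by exact two-sided permutation of the tables, and the order newborn, P10, P60 by an exact two-sided permutation of the Jonckheere-Terpstra statistic over 560 assignments. Tile differences were correlated across contrasts that share no table, with errors from leaving out each chromosome in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps, and limma 3.58.1 for an alternative test with a pseudocount of 1 read.

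The tile tests were tested on simulated data, with reads drawn from beta-binomial distributions for the real tiles and depths. All tiles had the same overdispersion, and changes were planted only in tiles of intermediate level. Recovery of changes in tiles of high or low level was therefore not simulated. In the simulated comparison of P60 with newborn (8651 tiles), edgeR recovered 4 of 67 tiles changed by 10 points, 47 of 67 changed by 20 points and 66 of 66 changed by 30 points, with 0 false calls. In that of GNMT KO with WT (11784 tiles) it recovered 2 of 67, 18 of 67 and 55 of 66, with 0 false calls. In that of db/db with db/+ (10396 tiles) it recovered 3 of 67, 23 of 67 and 51 of 66, with 4 false calls. The logistic test without overdispersion made 19 to 24 false calls in these simulations, and limma recovered 0 changed tiles in the comparisons of 2 with 2 tables.

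Design, tests, naming rule and most alternatives were fixed before the data were examined. Alternatives were the depth minimum, the upper depth limit, tile size and cytosines per tile, other tests and thresholds, the X chromosome, thinned reads, smaller fits, a replicate block and leaving out each replicate. Means over cytosines with at least 6 reads and tiles from cytosines at 50% or more were added after seeing the data. No 2 tables of a group were copies of each other: reads of every pair differed by more than sampling noise, with a chi-square per cytosine of 1.08 to 1.96. This does not show that the tables of a group come from separate pools. Promoters and gene lists were not analysed here, because no annotation of mm9 was used, and regions are given by mm9 position without gene names.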

Results

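DNA methylation of mouse sciatic nerve, the tissue in which Schwann cells form myelin, was followed in 3 settings. Wild-type nerves were taken from newborn mice (3 tables) and at postnatal days 10 (P10, 3 tables) and 60 (P60, 2 tables). Nerves of GNMT knockout (KO) and wild-type (WT) mice were taken at day 90. GNMT is glycine N-methyltransferase, an enzyme that consumes the methyl donor S-adenosylmethionine. Nerves of db/db mice, a model of type 2 diabetes that lacks a working leptin receptor, and of db/+ controls were taken at day 180. The GNMT and db groups had 2 tables each. Summed depth, the depths of all listed cytosines added up, ranged from 4032615 (newborn replicate 2) to 56482892 (P60 replicate 1). It is not a number of sequencing reads, since a read counts at each listed cytosine it covers. Summed depth was 4889923 and 5631945 in the GNMT KO tables, against 12924545 and 26614225 in GNMT WT. The tables listed 264280 to 1201725 cytosines.

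The mean level over all listed cytosines was lower in deeper tables. Pearson's r with log2 depth over the 16 tables was -0.851 (permutation p = 3e-05), and Spearman's rho was -0.909 (permutation p = 2e-05). Without the 2 tables farthest from the median depth r was -0.850. Within the 8 developmental tables r was -0.826 and rho -0.643, and within the 8 GNMT and db tables r was -0.909 and rho -0.881. Levels were therefore compared over cytosines shared by all tables of a series. A relation to depth may remain: the mean over shared cytosines was higher in deeper tables within each age, in GNMT WT and in db/db. In GNMT KO and db/+ the deeper table had the lower mean.

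**Figure D1:**
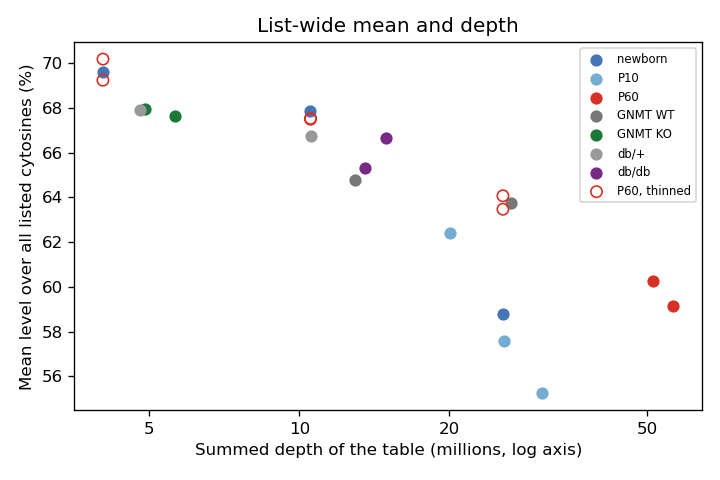
Each filled point is a call table, with summed depth (log axis) against the mean level over all listed cytosines in percent; open circles are the P60 tables after random removal of reads down to each newborn depth. The tables run from 69.6% in the shallowest newborn table to 55.2% in P10 replicate 3.

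Methylation over shared cytosines was higher at each later age. The mean level was 77.7% ± 0.135 in newborn nerve (SD, n = 3), 78.5% ± 0.242 at P10 (SD, n = 3) and 79.4% ± 0.114 at P60 (SD, n = 2). Every P10 table lay above every newborn table, and both P60 tables lay above every P10 table. Within each age the mean was also higher in deeper tables: from the shallowest to the deepest it was 77.6%, 77.7% and 77.9% in newborn nerve, 78.2%, 78.5% and 78.7% at P10 and 79.3% and 79.4% at P60. The P60 tables were the deepest, so age and depth were confounded for P60. Depths of newborn and P10 tables overlapped. Newborn replicate 3 (summed depth 25658439, mean 77.9%) was deeper than P10 replicate 1 (summed depth 20081849, mean 78.2%), yet had the lower mean. The exact two-sided permutation test of the trend gave p = 0.00357, the smallest it can give. The pairwise differences were 0.716, 1.62 and 0.902 percentage points for P10 against newborn, P60 against newborn and P60 against P10. Each had an exact permutation p of 0.1, the smallest these group sizes allow. The rise from newborn to P60 was 2.43 points for cytosines with a mean level of 20 to 50%, 2.03 points from 50 to 80% and 1.46 points from 80%, with separate tables in each class. Below 20% the difference was 0.425 points and the tables overlapped. Over all cytosines of each table with at least 10 reads, instead of the shared ones, later means were lower than the newborn mean, with differences of -7.46 points at P10 and -5.04 at P60. Weighting by reads gave differences of 3.50 points for P10 against newborn, 0.0820 for P60 against newborn and -3.42 for P60 against P10, and ended the trend (exact permutation p = 0.8). With at least 20 reads per cytosine the difference of P60 from P10 was 0.596 points.

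**Figure D2:**
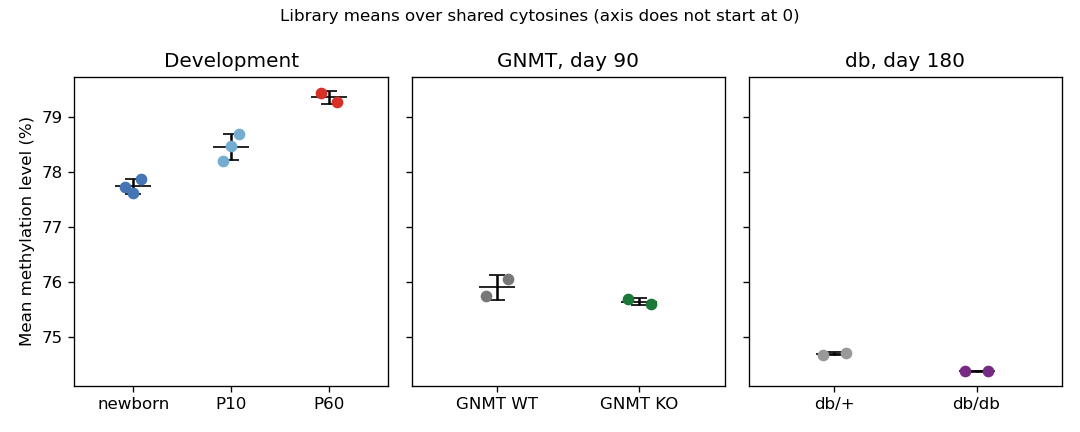
Mean methylation level in percent over shared cytosines, 1 point per call table, with group mean and SD; each panel has its own set of cytosines, so levels are compared within a panel. The newborn tables lie between 77.6% and 77.9%, and the P60 tables at 79.3% and 79.4%.

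From newborn to P60, which spans the formation of myelin, 69 of 8651 tiles changed, 49 with more and 20 with less methylation. The changes were spread over 18 chromosomes, and 39 were of at least 25 points. Of the 176 tiles under 20% in newborn nerve 8 gained and 1 lost, and of the 587 tiles at 20 to 50% 29 gained and 2 lost. Of the 2234 tiles at 50 to 80% 9 gained and 9 lost. Of the 5654 tiles at 80% or more, which had less room to gain, 3 gained and 8 lost. Tiles under 20% had less room to lose. The newborn level that sets the classes also enters the difference, so low classes lean to gains and high classes to losses by selection. The mean over the 49 gaining tiles was 39.8% ± 1.16 in newborn nerve (SD, n = 3), 57.7% ± 0.935 at P10 (SD, n = 3) and 66.2% ± 0.394 at P60 (SD, n = 2). The 20 losing tiles had 70.1% ± 0.833, 51.0% ± 2.59 and 39.9% ± 1.11 at these ages.

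The largest gain lay on chromosome 17 from 28488001 to 28489000 (mm9, 3 cytosines, 39 to 282 reads per table), from 19.3% ± 1.71 in newborn nerve to 63.2% ± 6.59 at P60 (log2 odds ratio 2.86, edgeR adjusted p = 0.00198). Chromosome 11 from 11731001 to 11732000 rose from 22.6% ± 4.79 to 66.4% ± 2.47 (edgeR adjusted p = 0.000911). On chromosome 8, the tile from 123920001 to 123921000 rose from 27.3% to 68.6% and that from 122916001 to 122917000 from 43.9% to 84.1% (edgeR adjusted p = 0.00974 for both). Chromosome 15 from 100593001 to 100594000 rose from 30.2% ± 6.73 to 70.8% ± 1.57 (edgeR adjusted p = 0.00198). The lowest p belonged to a loss on chromosome 19 from 5844001 to 5845000 (5 cytosines, 63 to 598 reads per table). It fell from 47.5% ± 7.50 in newborn nerve through 11.9% ± 4.98 at P10 to 2.26% ± 0.118 at P60 (log2 odds ratio -5.23, edgeR adjusted p = 1.17e-06). The largest loss with all tables, on chromosome 8 from 48565001 to 48566000, went from 93.3% ± 1.79 to 45.9% ± 3.88 (edgeR adjusted p = 0.00148); its difference of -47.4 points was -21.4 without newborn replicate 2. Chromosome 11 from 98582001 to 98583000 went from 80.8% ± 6.20 to 34.2% ± 1.38 (edgeR adjusted p = 0.000234). Losses also lay on chromosome 13 from 55608001 to 55609000 (75.1% to 38.6%; a difference of -36.5 points, and of -22.7 without newborn replicate 2) and on chromosome 5 from 31947001 to 31948000 (75.3% to 39.9%, edgeR adjusted p = 0.0308). The chromosome 5 tile was not called with thinned reads (edgeR adjusted p = 0.123) or without any 1 newborn or P60 replicate (0.104 to 0.232). Both gains on chromosome 8 lost their calls without newborn replicate 1 or 3 or either P60 replicate (edgeR adjusted p from 0.0599 to 0.135). The chromosome 17 gain did without newborn replicate 3 (0.0599) or P60 replicate 1 (0.0509), the chromosome 15 gain without P60 replicate 1 (0.0514) and the chromosome 13 loss without P60 replicate 2 (0.0579).

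**Figure D3:**
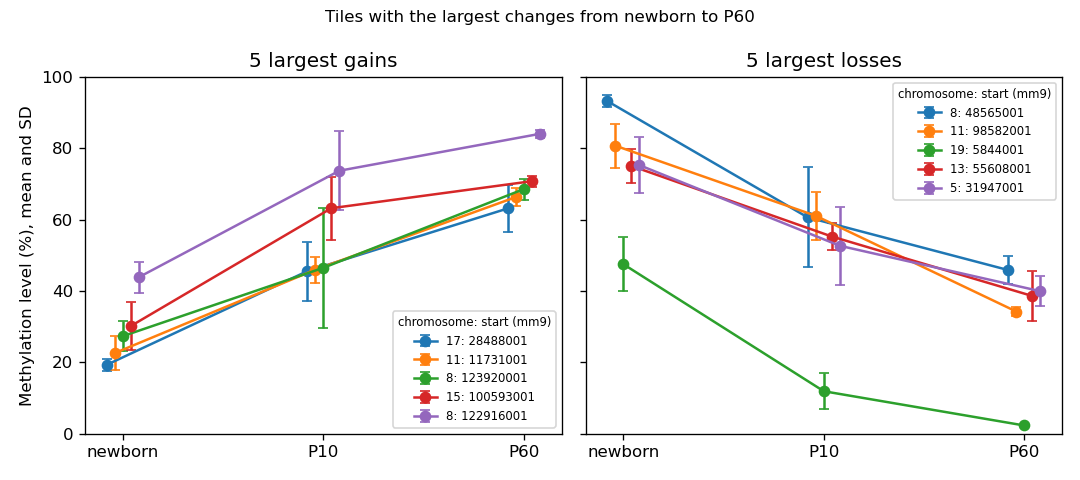
Methylation level in percent (mean and SD) at newborn (n = 3), P10 (n = 3) and P60 (n = 2) of the 5 tiles with the largest gains and the 5 with the largest losses between newborn and P60, offset sideways for legibility. Each of the 10 tiles has its P10 mean between the newborn and P60 means.

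Before any correction, 1073 tiles had an edgeR p under 0.05 between P60 and newborn, 869 higher and 204 lower. The tables did not overlap in 2537 tiles (29.3%, against 20% by chance for 3 against 2), 1982 higher and 555 lower at P60. The count of called tiles was 13 without P60 replicate 1, 18 without P60 replicate 2, 22 without newborn replicate 1 and 16 without newborn replicate 3. More tiles were tested without newborn replicate 2 (143 of 21917 called) and without P10 replicate 1 (132 of 9750) than the 8651 with all tables. Limma on logit levels called 3 tiles, and thinning all tables to the depth of the shallowest left 24. EdgeR called 1 of 1343 tiles with at least 20 reads per cytosine and 179 of 22363 with at least 5 reads. With only these groups in the fit it called 185 of 10473.

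From newborn to P10, 27 tiles changed, 22 with more and 5 with less methylation. The mean over the 22 gaining tiles was 39.6% ± 1.40 in newborn nerve, 62.5% ± 0.989 at P10 and 61.9% ± 0.207 at P60. The largest gain lay on chromosome 4 from 116969001 to 116970000, from 38.8% ± 6.85 to 74.9% ± 13.1 (edgeR adjusted p = 0.0103). Chromosome 11 from 85699001 to 85700000 rose from 44.5% ± 5.60 to 78.3% ± 1.64 (edgeR adjusted p = 0.00211) and had 79.2% at P60. The tile on chromosome 15 named above also rose, to 63.2% ± 8.87 (edgeR adjusted p = 0.0171). Chromosome 1 from 90696001 to 90697000 rose from 33.5% to 66.3% (edgeR adjusted p = 0.0302), and chromosome 8 from 124860001 to 124861000 from 44.5% to 75.0% (edgeR adjusted p = 0.0344). All 5 losses are named. The tiles on chromosome 19 (47.5% to 11.9%) and chromosome 8 from 48565001 (93.3% to 60.7%) were among the losses to P60 too; without newborn replicate 2 the latter differed by -14.4 points and was not called (edgeR adjusted p = 0.0970). Chromosome 9 from 103129001 to 103130000 fell from 66.2% ± 1.81 to 37.6% ± 8.31, and chromosome 5 from 124454001 to 124455000 from 81.3% ± 2.79 to 55.4% ± 2.29 (edgeR adjusted p = 0.0171 and 0.00411). Chromosome 10 from 75052001 to 75053000 fell from 49.9% ± 3.16 to 26.8% ± 4.41 (edgeR adjusted p = 0.00235) and had 18.9% ± 3.11 at P60. Of these 10 tiles only that on chromosome 19 stayed called by edgeR without newborn replicate 3 (adjusted p of the others from 0.0783 to 0.344). Those on chromosomes 1, 4, 8, 9 and 15 were not called without newborn replicate 1 (edgeR adjusted p from 0.107 to 0.194) or newborn replicate 2 (0.0588 to 0.114). Calls were also lost without P10 replicate 3 on chromosomes 1, 4 and 9 and for the chromosome 8 loss (0.0539 to 0.0635). The chromosome 8 gain was not called without P10 replicate 2 (0.156), nor were it and the chromosome 1 tile without either P60 replicate (0.0605 to 0.0618). Tables did not overlap in 13.8% of tiles, against 10% by chance for 3 against 3. The count was 8 without newborn replicate 1, 1 without newborn replicate 3, 17 without P60 replicate 1, 60 without P10 replicate 1 and 0 with limma.

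Between P10 and P60, 2 of 8651 tiles changed. Chromosome 2 from 84712001 to 84713000 rose from 26.0% ± 3.77 at P10 to 53.7% ± 0.268 at P60, with 18.3% in newborn nerve. Its difference of 27.7 points was 14.9, and not called, with at least 5 reads per cytosine or with only these groups in the fit. Chromosome 5 from 29918001 to 29919000 fell from 89.5% ± 5.47 to 58.7% ± 2.03, with 67.9% in newborn nerve (edgeR adjusted p = 0.0288 for both). Its difference was unchanged with only these groups in the fit, where it was not called (edgeR adjusted p = 0.331). Neither tile was called with thinned reads, or without any 1 replicate other than P10 replicate 1 (edgeR adjusted p from 0.0593 to 0.369). At an unadjusted edgeR p under 0.05 there were 687 tiles, 462 higher and 225 lower at P60. The quasi-binomial logistic model called 34 tiles and the logistic test without overdispersion 279. The count was 0 with limma, 8 without P10 replicate 1 and 0 without any 1 of newborn replicates 1 to 3, P10 replicate 2 or the P60 replicates.

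Between GNMT KO and WT nerves no tile of 11784 was called by edgeR. At an unadjusted edgeR p under 0.05 there were 631 tiles (260 higher and 371 lower in KO), near the 5% that chance gives. Limma also called 0 tiles, the quasi-binomial logistic model 12 and the logistic test without overdispersion 109. In simulated tables of this size, with changes only in tiles of intermediate level, edgeR found 18 of 67 tiles changed by 20 points and limma none. So 0 calls leave room for changes of that size. Most tiles (7334 of 11784 at 80% or more in WT) lay outside that range of levels. The tile of lowest p, chosen after its values were seen, lay on chromosome 17 from 39982001 to 39983000 (40 cytosines, 6270 to 17944 reads per table), at 22.1% ± 0.767 in KO and 16.7% ± 0.232 in WT (SD, n = 2; edgeR adjusted p = 0.250). Its 5.42 points lie under the minimum of 10, so no alternative called it, although its adjusted p was under 0.05 in 5 of 14. These p ranged from 4.63e-35 by the logistic test without overdispersion to 1 by edgeR without GNMT KO replicate 1, and were 0.0267 by edgeR with at least 5 reads and 0.0107 without an upper depth limit. The mean level over shared cytosines was 75.6% ± 0.0656 in KO and 75.9% ± 0.226 in WT (SD, n = 2). The difference of -0.259 points had an exact permutation p of 0.33, the smallest that 2 against 2 can give; it was -0.0857 points without GNMT WT replicate 2, -0.148 with at least 20 reads, -1.33 weighted by reads and 3.20 over all cytosines of each table. Depth moved with genotype: both KO tables were shallower than both WT tables. The deepest table, GNMT WT replicate 2, also had the highest mean (76.1%, against 75.7% in GNMT WT replicate 1). Of the KO tables the shallower, replicate 1, had the higher mean (75.69% against 75.59%). Since depth moved with genotype, the mean differences between KO and WT and those by class are not separated from depth. By class of level, KO tables lay below WT tables at 50 to 80% (68.6% against 70.0%) and at 20 to 50% (34.3% against 35.3%), and above them below 20% (11.1% against 10.5%) and from 80% (by 0.124 points). Tables did not overlap in 35.3% of tiles, against 33.3% by chance for 2 against 2.

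Between db/db and db/+ nerves no tile of 10396 was called by edgeR. At an unadjusted edgeR p under 0.05 there were 489 tiles (221 higher and 268 lower in db/db), near the 5% that chance gives. Limma called 0 tiles, the quasi-binomial logistic model 5 and the logistic test without overdispersion 65. In simulated tables of this size, with changes only in tiles of intermediate level, edgeR found 23 of 67 tiles changed by 20 points and limma none. EdgeR made 4 false calls there and the quasi-binomial model 7. Most tiles (6173 of 10396 at 80% or more in db/+) lay outside that range of levels. The tile of lowest p, chosen after its values were seen, was the one on chromosome 10 from 75052001 that lost methylation with age. It had 30.5% ± 3.00 in db/db and 10.6% ± 0.261 in db/+ (SD, n = 2, 5 cytosines, 125 to 299 reads per table; log2 odds ratio 1.86, edgeR adjusted p = 0.136). It was called in 5 of 14 alternatives, among them at least 20 reads per cytosine (edgeR adjusted p = 0.0151), and without any 1 replicate it was not called; over edgeR and the other tests the adjusted p ranged from 1.19e-08 to 0.993. The mean level over shared cytosines was 74.4% ± 0.00557 in db/db and 74.7% ± 0.0266 in db/+ (SD, n = 2), a difference of -0.316 points (exact permutation p = 0.33). It was -0.210 without db/+ replicate 2, -0.725 over all cytosines of each table and 0.699 weighted by reads. Depth moved with genotype here too. Summed depth was 14932739 and 13554731 in the db/db tables, against 10535282 and 4789749 in db/+. The mean difference between db/db and db/+ is therefore not separated from depth. Tables did not overlap in 33.2% of tiles, against 33.3% by chance for 2 against 2.

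**Figure D4:**
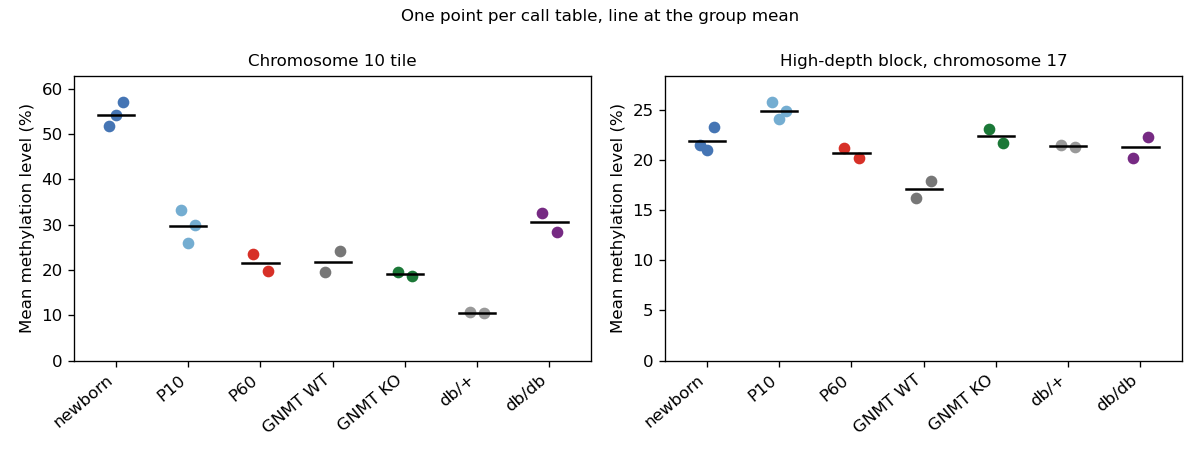
Mean methylation level in percent over cytosines with at least 10 reads in all 16 tables, 1 point per table and a line at the group mean, for the chromosome 10 tile and for a block of high depth on chromosome 17 from 39979001 to 39986000. In the tile db/+ tables lie at 10.4% and 10.7% and db/db tables at 28.4% and 32.7%; in the block GNMT WT tables lie at 16.2% and 17.9%.

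Changes were compared across the settings, which share no table. Over 5982 tiles measured in both, the change from newborn to P60 was not correlated with that from GNMT WT to KO (Pearson's r = -0.00373, jackknife SE 0.0168; Spearman's rho = -0.0234). With the change from db/+ to db/db it had a weak negative correlation over 5160 tiles (r = -0.0631, jackknife SE 0.0119; rho = -0.0359), which was r = -0.110 (jackknife SE 0.0177) over the 1600 tiles with a mean level of 20 to 80%. It was r = -0.0320 without db/+ replicate 1 and r = -0.0387 without db/db replicate 2. With at least 20 reads per cytosine, over 1005 tiles, r was -0.00173 (jackknife SE 0.0533). The GNMT and db changes had r = -0.00725 (jackknife SE 0.0123) over 7261 tiles. These correlations are across tiles, which are not independent replicates. No tile was called in 2 settings, since GNMT and db had 0 calls.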

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

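The tests of the X chromosome were planned as an alternative; mice of either sex were pooled, so it stayed outside the main comparisons. A pair of regions on it passed the thresholds of the autosomes, out of 324 tiles tested. The tile from 166436001 to 166437000 (mm9, 14 cytosines) had 40.8% ± 2.32 in newborn nerve, 52.9% ± 3.83 at P10 and 57.8% ± 1.58 at P60, a difference of 12.1 points at P10 (edgeR adjusted p = 0.0109) and of 17.01 points at P60 (edgeR adjusted p = 0.000705). The tile from 90534001 to 90535000 (3 cytosines) had 11.6% ± 3.46 in newborn nerve, 7.79% ± 1.03 at P10 and 46.7% ± 3.24 at P60. Its P60 level was 35.2 points above newborn (edgeR adjusted p = 0.0232) and 38.9 points above P10 (edgeR adjusted p = 0.0143). No X tile was called between GNMT KO and WT or between db/db and db/+ (edgeR, 374 and 569 tiles). The sex ratio of the pools was not given in the sources used here. The share of listed depth on the X chromosome, capped at 500 per cytosine, was 4.54 to 5.29% in newborn tables, 4.04 to 4.19% at P10 and 4.66 to 4.68% at P60. Shares on the Y chromosome overlapped between the ages. Among these tables newborn replicate 2 had both the highest X share (5.29%) and the highest Y share (0.203%). Such shares depend on depth and on which cytosines a table lists, so they do not measure the sex ratio. It may differ between the pools compared, and no explanation was tested.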

How the results depend on the processing

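For the age comparisons, counts of called tiles moved by over 1.5 times under most alternatives. Between GNMT KO and WT the count stayed at 0 in 15 of 18 alternatives, and between db/db and db/+ in 13 of 18. In some alternatives fewer tiles, reads or tables entered, and why counts moved was not tested. For P10 against newborn (27), P60 against newborn (69) and P60 against P10 (2) the counts were as follows: 3, 21 and 0 at an adjusted p under 0.01 and 25 points; 57, 140 and 34 with the quasi-binomial model; 388, 494 and 279 with the logistic test without overdispersion; 0, 3 and 0 with limma. They were 17, 31 and 0 with at least 5 cytosines per tile, 2, 1 and 3 with at least 20 reads, 72, 179 and 2 with at least 5 reads, and 18, 24 and 0 with thinned reads. With only the groups compared in the fit they were 17, 185 and 0. With cytosines at 50% or more, chosen after seeing the data, they were 10, 32 and 1. For P60 against P10 the count was 5 without a minimum difference and 7 without an upper depth limit. Leaving out 1 replicate gave 1 to 60, 13 to 143 and 0 to 8. GNMT KO against WT went from 0 to 12 with the quasi-binomial model and 109 without overdispersion. For db/db against db/+ these were 5 and 65, and it was 1 with at least 20 and 1 with at least 5 reads. Leaving out 1 replicate kept both at 0; a lone table was then assumed to vary like the other group.

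Replicate numbers did not pair the tables: the correlation of same-number deviations lay between -0.0149 and 0.0230. With the replicate block the counts were 29 for P10 against newborn, 34 for P60 against newborn, 3 for P60 against P10 (0 higher and 3 lower), 10 for GNMT (5 higher and 5 lower) and 4 for db. Of the named tiles, the chromosome 2 gain to P60 (adjusted p = 0.0826) and the chromosome 5 loss from 31947001 (0.109) were then not called, the chromosome 10 tile was called in db (2.38e-05), and the chromosome 17 tile in GNMT had 4.28e-05 at 5.42 points, and no mean difference changed direction (0.716, 1.69, 1.02, -0.259 and -0.316 points in that order).

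Over all cytosines of each table, the mean differences turned to -7.46 points (P10 against newborn), -5.04 (P60 against newborn) and 3.20 (GNMT), and the trend statistic went from 1 to 0.33 of its maximum. They moved by over 1.5 times to 2.42 (P60 against P10) and -0.725 (db). Weighting by reads gave 3.50 points for P10 against newborn, 0.0820 for P60 against newborn, -3.42 for P60 against P10, -1.33 for GNMT, 0.699 for db and a trend of 0.571 that no longer passed. Also moved by over 1.5 times were P60 against P10 (0.596) and GNMT (-0.148) with at least 20 reads, GNMT without GNMT WT replicate 2 (-0.0857) and db without db/+ replicate 2 (-0.210). In the other alternatives, those with at least 6 reads chosen after seeing the data included, mean differences kept their direction within 1.5 times and the trend passed; without 1 replicate each the trend stayed at 1.

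The correlation of the changes with age and in GNMT KO was near 0 throughout and changed sign: 0.00618 for tiles at 20 to 80%, 0.0291 with at least 20 reads, and -0.0111 to 0.0197 without 1 replicate. That with age and in db/db was -0.110 for tiles at 20 to 80%, -0.0320 to -0.0699 without 1 replicate, and no longer exceeded 2 SE with at least 20 reads (-0.00173). That between GNMT and db was 0.0147 with at least 20 reads and -0.0254 to 0.0208 without 1 replicate; it exceeded 2 SE without GNMT WT replicate 1 (-0.0242) and without GNMT KO replicate 1 (-0.0254).

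For the tiles named by rule, the call was lost in 45 of 179, 29 of 177 and 22 of 35 values for the 3 age comparisons, and no direction turned. Limma called of them only the chromosome 11 gain from 11731001 and the chromosome 19 loss, both to P60. Thinned reads ended the calls of the chromosome 1, 8 (124860001) and 9 tiles at P10, of 8 (123920001 and 122916001) and 5 (31947001) at P60, and of both between P10 and P60. Differences moved by over 1.5 times without newborn replicate 2 in the chromosome 8 tile from 48565001 (-32.7 to -14.4 points at P10, -47.4 to -21.4 at P60) and the chromosome 13 tile (-36.5 to -22.7). The chromosome 2 tile went from 27.7 to 14.9 points with at least 5 reads and with only the groups compared. The chromosome 10 tile differed between GNMT KO and WT by 0.702 points without GNMT WT replicate 2 and 0.830 without GNMT KO replicate 2, by -3.06 without GNMT KO replicate 1, -2.93 without GNMT WT replicate 1, -2.46 with at least 20 reads and -2.85 with thinned reads, against -1.11 with all tables. Promoters and gene lists were not run. Depth limited the tile tests: newborn replicate 2 had a summed depth of 4032615, and only 1343 tiles had 20 reads per cytosine in every developmental table.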

Other observations

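The tests of age-called tiles in the other mice, of thinned reads and of other splits were fixed before their results were seen; the tests of depth within ages, of conversion, of the listing rule at high levels and of the chromosome 17 block were chosen after. The limits of that block were set 3 times, after its values were seen; the last are used, and the tests were not compared between them.

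The tiles that changed between newborn and P60 had similar levels in adult nerves of other mice. Of 45 such tiles measured in GNMT WT (day 90), 39 lay nearer to the P60 than to the newborn level, and of 37 measured in db/+ (day 180), 32 did. Over the 29 gaining tiles measured in GNMT WT the mean was 42.2% in newborn nerve, 66.1% at P60 and 64.5% in GNMT WT; over the 16 losing tiles it was 72.1%, 43.3% and 48.1%. Of 31 tiles measured in all, 74.2% lay nearer to P60 in both groups. This is consistent with a level reached by P60 that is kept in adult nerve; age, colony and sequencing run were not separated.

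A hypothesis that nerves of GNMT KO or db/db mice return towards the newborn state was tested on the same tiles. Of the 45 tiles, 42.2% differed between KO and WT in the direction opposite to age (mean shift along age 1.17 points, SD 6.21 over tiles; exact sign test over tiles, p = 0.371), and the correlation of the changes over all tiles was near 0 (r = -0.00373, jackknife SE 0.0168). In db/db, 56.8% of 37 tiles did (mean shift -0.984 points, SD 9.21; exact sign test over tiles, p = 0.511). The correlation over all tiles ran in the direction of a return in db/db (r = -0.0631, jackknife SE 0.0119; -0.110 for tiles at 20 to 80%), but was -0.00173 with at least 20 reads per cytosine. The bounds set were over 67% for a return and under 50% against it. The GNMT KO share lay under 50%, but its 95% binomial interval (27.7% to 57.8%) includes 50% and not 67%. That of db/db (39.5% to 72.9%) includes both. The sign tests and these intervals treat tiles as independent, but all tiles of a comparison come from the same few tables. Neither measures the spread between replicates, so the hypothesis of a return stays open in GNMT KO and in db/db.

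The chromosome 10 tile (75052001 to 75053000), whose db values were seen before this test, was higher in db/db than in db/+, opposite to its change with age. Over 5 cytosines measured in all 16 tables it fell from 54.3% ± 2.71 in newborn nerve to 29.7% ± 3.61 at P10 and 21.6% ± 2.69 at P60. It stood at 21.9% ± 3.24 in GNMT WT, 19.04% ± 0.651 in GNMT KO, 10.6% ± 0.240 in db/+ and 30.6% ± 3.01 in db/db. Against P60 and both GNMT groups, db/+ lay lower and db/db higher. A change in db/db thus cannot be told apart from a level particular to the db/+ tables. The tile had the lowest p among 10396 and did not pass the correction.

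The mean over all listed cytosines was lower at P60 than in newborn nerve on average, although it was higher over shared cytosines. The gap was 9.04 points against newborn replicates 1 and 2, and there was none against newborn replicate 3 (58.8%, against 59.1% and 60.2% in the P60 tables). The P60 tables were thinned to the newborn depths, and cytosines were listed again only above 5 reads with at least 1 methylated read. This closed 98.7% of the gap against replicates 1 and 2. However, the thinned tables listed 365883 and 380194 cytosines at the depth of newborn replicate 1, which listed 573692. At the depth of newborn replicate 2 they listed 87371 and 85804, against 264280. They held fewer cytosines than these newborn tables, so the closed share does not decide whether a listing rule that depends on depth accounts for the gap. Over the 3 replicates together thinning closed 128%, a figure raised by replicate 3. That replicate lay below P60 tables thinned to its depth (63.5% and 64.1%), so thinning moved the P60 means away from its mean.

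The rise over shared cytosines with age was weighed against technical sources. Less complete conversion at P60, large enough to raise the class from 80% as seen, would have raised the class below 20% by 12.4 points. That class rose by 0.425 (SE 0.481), 3.42% of it. However, no listed cytosine was shown to lack methylated reads, which keeps up the lowest levels in shallow newborn tables. The classes were also set by a mean level that includes the P60 tables, so cytosines raised at P60 can leave the lowest class. Both can hold down the rise of that class, so its small rise does not decide on conversion. The requirement of a methylated read in every table binds little at high levels, and the class from 80% still rose by 1.46 points. For P60 against newborn, depth cannot be told apart from age. The slope within ages would bring 20.3% of the rise (95% interval -12.4% to 52.9%). However, that slope was 0.10 points per doubling in newborn nerve, 0.783 at P10 and 1.19 at P60. Age itself, a changed mix of cell types and differences between sequencing runs remain possible explanations and were not tested.

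A block on chromosome 17 from 39979001 to 39986000 (255 cytosines) had 499 to 3562 reads per cytosine (median per table), where the median tile of the GNMT tables had 27.8. The block was lower in GNMT WT (17.04% ± 1.19) than in GNMT KO (22.4% ± 1.001). It was extended over adjoining tiles of high depth from the tile of lowest p between GNMT KO and WT. Part of this difference is therefore selected. The 12 tables of the other groups ranged from 20.1% to 25.8%, and 0 of the KO tables but both WT tables lay outside that range. These are other mice at other ages, so a change in GNMT KO cannot be told apart from a level particular to the WT tables. The share of listed depth in the block was 1.36 times as high in KO as in WT. Within the other groups the level changed by -0.240 points per percent of listed depth (95% interval -1.47 to 0.992), where the GNMT difference needs 6.37. That share also depends on which other cytosines a table lists, so it is not a direct measure of copies. The slope therefore does not decide whether the number of copies read differed between KO and WT.

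The 27 tiles called between P10 and newborn were set against the other splits of the 6 tables into groups of 3. Of the 10 splits, 1 gave as many, the real one, and the highest of the others gave 0; the splits are too few for a share under 0.05.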
